A study of Mus musculus with 2 samples.

How the data were processed

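Adrenal glands of adult mice were measured by stranded, paired-end RNA sequencing of poly(A) RNA in 2 libraries, which the labels call biological replicates of 1 experiment. The replicate numbers were taken from the labels. Both libraries form 1 group, and no sample was left out.

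The deposited gene and transcript tables give 1 library each. Per the file headers they hold an expected count, a TPM and an FPKM value for each gene, together with a posterior mean of the count and of TPM. They were derived from alignments to the transcriptome of mm10 with the M4 annotation, per the readme files deposited beside them. The aligner and the quantifier with their versions are not given in the sources used here. An expected count is the deposited estimate of read pairs per gene, not normalized, and it is fractional where the authors split reads between genes that share sequence. The authors' TPM is scaled to a fixed total over all genes and spike-ins, and the authors' FPKM is scaled by gene length and by the number of fragments. The deposited contig table in mm9 has a coverage signal summed over the contig and the authors' score. Its direction is not stated in the sources used here, and low values were taken to mean better reproducibility from the file format, so the counts of junctions and contigs that pass rest on this reading. The deposited junction table in mm9 has a read count per junction, which equals the sum of the values R1 and R2 in the name field, and the authors' score. R1 and R2 were not assigned to the samples. As a check of the score's direction, 97.4% of the passing junctions had reads in both R1 and R2, against 128817 of all 378838. No such check was made for contigs. No replicate is given for either mm9 table, so both were taken as pooled, and the tool that made them is not given in the sources used here. The score's range was 0 to 0.83 for junctions and 0 to 0.69 for contigs.

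The gene tables held 69691 rows. Of these, 43346 were mouse gene identifiers, 96 were ERCC spike-in RNAs, 1 was the phiX174 sequence and 26248 were numeric identifiers that had 0 counts in both libraries. Names, gene types and positions were matched by identifier without version to GENCODE M21 on the same assembly, GRCm38. This matched 42462 identifiers. The other 884 held 0.111% of the counts in each library and keep their identifiers. ERCC spike-ins took 0.654% of the expected counts in replicate 1 and 0.485% in replicate 2. Spike-ins and phiX174 were left out of library sizes, tests and TPM shares.

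Depth was 48059863 expected counts in replicate 1 and 53294872 in replicate 2. Over the 15814 genes with a summed count of at least 20, a chi-square comparison gave 103 per gene, so the libraries differ by far more than counting noise and are not repeats of 1 library. The SD of the log2 ratio fell from 1.32 for genes with a summed count of 20 to 100 to 0.38 for genes between 1000 and 10000 counts, so ratios of low genes are less precise. Intervals and limits cover counting error only, since amplified reads are not independent molecules.

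Levels are means with SD over both libraries. A gene was called detected at 1 TPM or more in both. The share of a list is its summed TPM over all TPM outside spike-ins. For the comparison of the libraries, expected counts were rounded to whole numbers for the test, and scaled with TMM factors of 1.00 and 0.999 from edgeR 4.0.16 in R 4.3.3, giving effective library sizes with a ratio of 1.11. A two-sided exact binomial test was run for each gene in scipy 1.17.1 with Benjamini-Hochberg adjustment, a threshold of 0.05 and a minimum of 2-fold. The log2 ratio used scaled counts plus a prior count of 0.5, and its 95% interval is exact (Clopper-Pearson). For a gene at 0 in a library the fold is a lower bound against 3 counts in that library. A list's median log2 ratio, for lists with at least 3 tested members, was placed among 10000 random lists of its size matched on mean expression in 20 bins. Such a percentile describes these libraries and is no test of conditions. The comparison of 1 library with the other leaves no residual spread for a replicated test. Levels, shares and ratios within the tissue have 1 residual degree of freedom and are given with their SD or per library, without a test.

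The 25 gene lists with 237 genes, the tests and the rule for named genes were fixed before the data were examined. The rule takes the members of the lists, the 15 genes with the highest mean TPM and, of the genes past the threshold with a mean count of at least 50, the 10 highest and the 10 lowest log2 ratios. A sympathetic neuron list, a second adipose list and a second clock list were added later for the closing tests.

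On simulated counts for the comparison of replicate 1 with replicate 2 (15683 genes, 200 of them changed), the test recovered 85% of genes changed 2.5-fold and 92% of those changed 4-fold, and called 0 of 15483 unchanged genes. In the same simulation 1 list moved by 0.5 on the log2 scale lay at percentile 100 and 1 unmoved list at percentile 38.8. The simulated counts held counting error only, whereas the real libraries differ by far more. The simulation therefore checks the calculation and does not show the rate of false calls in these data.

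Alternatives tried were posterior mean TPM and FPKM, each library alone, other detection limits, pseudocounts of 0.1 and 0.01, DESeq2 1.42.0 size factors, total counts and spike-in counts for scaling, other count minimums, posterior mean counts, edgeR's exact test with an assumed coefficient of variation of 0.1 and 0.2, no minimum fold, list means, and other score, read and length limits for junctions and contigs. Random lists also matched on gene length, protein-coding genes only and genes with whole counts only (within 0.005) were added after seeing the data. Calculations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.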

Results

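The adrenal gland of adult C57BL/6J mice was profiled by RNA sequencing at 8 weeks of age. The labels describe the animals as littermates of mixed sex. There was 1 group with 2 libraries, labelled biological replicates 1 and 2. RNA longer than 200 nt was depleted of ribosomal RNA and selected for poly(A), and stranded libraries were read as pairs of 76 nt on an Illumina GAIIx with added spike-in RNAs. The expected counts summed to 48059863 in replicate 1 and 53294872 in replicate 2. With a single group the design implies no comparison between conditions. The data answer which genes the gland expressed, at what level, and how far the replicates differed. Values below are the mean of both libraries with their SD (n = 2), in TPM, the share of a transcript scaled to a fixed total.

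Transcripts of the steroid-producing cortex were among the most abundant in the gland. Cyp21a1, the steroid 21-hydroxylase (ENSMUSG00000024365.9, mm10 chromosome 17, 34801348 to 34804561, minus strand), stood at 16912 ± 3435 TPM, second only to the ferritin heavy chain Fth1 at 21384 ± 2503 TPM. The mitochondrial electron carrier Fdx1 was at 3410 ± 705 TPM and its reductase Fdxr at 2295 ± 191 TPM. Hsd3b1, which makes progesterone from pregnenolone, was at 3050 ± 309 TPM. Star (mm10 chromosome 8, 25806555 to 25815982), which moves cholesterol into mitochondria, was at 2329 ± 694 TPM, and Cyp11a1, which cleaves the cholesterol side chain, at 1703 ± 294 TPM. The lipoprotein receptor Scarb1 was at 2580 ± 312 TPM and the transcription factor Nr5a1 at 1131 ± 412 TPM. The 20 genes of the steroidogenesis list together held 3.79% ± 0.530 of all TPM outside spike-ins, and 16 of them exceeded 100 TPM in both libraries. Cyp17a1, the 17-hydroxylase, was at 0.190 ± 0.0141 TPM with 10 counts in replicate 1 and 8 in replicate 2, and was the single member below 1 TPM. Some of these genes have near-identical relatives or pseudogenes with which reads were shared, so their levels carry that uncertainty.

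Enzymes of different cortical zones differed in level. Cyp11b1, the 11-hydroxylase of the zona fasciculata (mm10 chromosome 15, 74834125 to 74841643), was at 1352 ± 418 TPM, and the neighbouring aldosterone synthase gene Cyp11b2 (74851010 to 74856318) was at 126 ± 10.6 TPM. The ratio of Cyp11b1 to Cyp11b2 was 8.94 in replicate 1 and 12.4 in replicate 2. Hsd3b1 exceeded Hsd3b6, the form known from the zona glomerulosa, 134-fold in replicate 1 and 149-fold in replicate 2. All 8 glomerulosa genes were detected in both libraries, with Dab2 at 153 ± 36.0 TPM, Wnt4 at 91.8 ± 20.8 TPM and Shh at 47.1 ± 17.3 TPM. Of the fasciculata list, Akr1b7 was at 390 ± 101 TPM and the ACTH receptor Mc2r at 205 ± 84.0 TPM, while Frmpd4 was at 0.565 ± 0.106 TPM. The X zone marker Akr1c18 was at 179 ± 63.4 TPM. The capsule list was detected in full, led by Nr2f2 at 144 ± 16.2 TPM, with Gli1 at 10.4 ± 1.29 TPM and Rspo3 at 25.7 ± 5.85 TPM. These ratios were not tested, since 2 libraries leave 1 residual degree of freedom. In both libraries the higher enzyme of each pair exceeded the lower by far more than the replicates of either differed.

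The catecholamine-producing medulla was also represented. All 20 genes of the chromaffin list reached 1 TPM in both libraries, and together they held 0.469% ± 0.0562 of TPM. Chga, a core protein of secretory granules, was highest at 2252 ± 238 TPM, followed by the peptide gene Npy at 672 ± 288 TPM. The enzymes of catecholamine synthesis Pnmt, Th and Dbh were at 487 ± 150, 467 ± 33.1 and 313 ± 7.89 TPM. Ddc, the decarboxylase of the same pathway, was lower at 12.2 ± 1.65 TPM. Th over Pnmt was 1.29 in replicate 1 and 0.749 in replicate 2, so that the order of these enzymes differed between the replicates. Dbh over Pnmt was 0.807 and 0.538. The vesicular transporter Slc18a1 was at 14.9 ± 1.06 TPM and Slc18a2 at 6.17 ± 3.05 TPM.

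**Figure D1:**
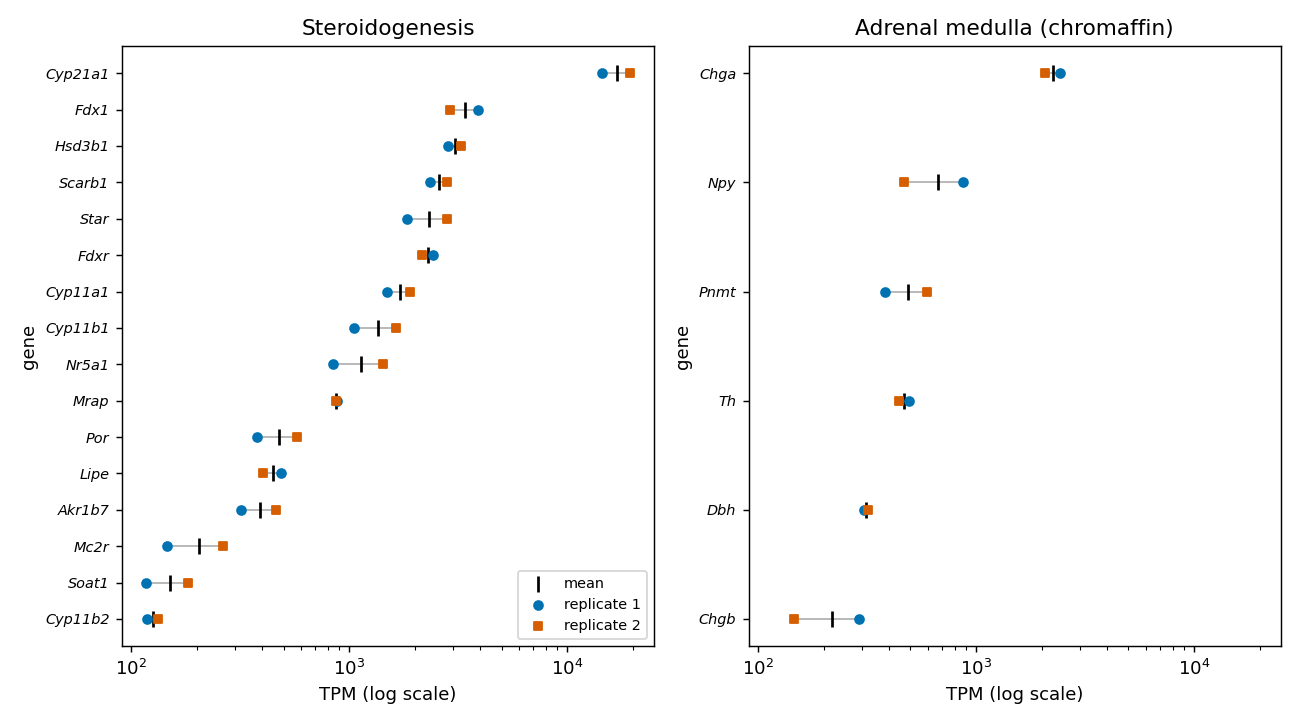
Each row is a gene of the steroidogenesis list (left) or the chromaffin list (right) that reached 100 TPM in both libraries, and the horizontal axis is TPM on a log scale. Blue circles are replicate 1, orange squares replicate 2 and black ticks their mean. Cyp21a1 lies at 14483 TPM in replicate 1 and 19341 TPM in replicate 2, and Chga at 2420 and 2083 TPM.

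The highest genes of the gland besides Fth1 and Cyp21a1 belonged to several programmes. They included the ferritin light chain Ftl1 at 7204 ± 326 TPM, the ribosomal protein gene Rplp1 at 11554 ± 942 TPM, the ATP synthase subunits Atp5b at 8419 ± 1805 TPM and Atp5d at 6302 ± 642 TPM, and the mitochondrial protein gene Chchd10 at 6076 ± 1832 TPM. Fasn, the fatty acid synthase, was at 7986 ± 1745 TPM, Igfbp7 at 7604 ± 2961 TPM and the adipocyte gene Cfd at 6934 ± 4171 TPM. The non-coding RNAs Rn7s1, Rn7s2 and Rn7sk were also among the 15 highest. The libraries were selected for poly(A), so the values of these non-coding RNAs may not reflect their level in the gland. Rn7s1 and Rn7s2 were given identical values of 8008 ± 2564 TPM, since their reads cannot be told apart, and Rn7sk was at 5994 ± 308 TPM. The mitochondrially encoded mt-Co1 was at 7362 ± 180 TPM, and the mitochondrial pseudogene Gm29216 on chromosome 1, which shares reads, at 6901 ± 373 TPM. The 15 genes together took 14.3% of TPM in replicate 1 and 13.3% in replicate 2. The 13 mitochondrially encoded genes held 1.81% ± 0.209 of TPM. Most of these genes had fractional counts shared with other loci, so the share carries that uncertainty. mt-Nd3 was listed at 0 in both libraries.

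In all, 12445 genes reached 1 TPM in both libraries, of which 11718 (94.2%) were protein-coding. Among the rest were 163 processed pseudogenes, 155 antisense genes and 106 lincRNAs. Above 100 TPM in both libraries stood 1508 protein-coding genes. Across the 20016 genes above 0 in at least 1 library, log2(TPM + 1) of the replicates correlated with a Pearson r of 0.988 and a Spearman rho of 0.972. This correlation is across genes, which are not independent replicates.

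Transcripts of other cell types and tissues were measured in the same libraries. The adipose list had all 10 members at 1 TPM or more and held 1.15% ± 0.617 of TPM, with 1.59% in replicate 1 and 0.718% in replicate 2. Cfd, Car3 (1757 ± 823 TPM) and the brown fat uncoupling protein Ucp1 (837 ± 413 TPM) were its most abundant members. Endothelial markers held 0.0923% ± 0.00965, led by Plvap at 642 ± 67.8 TPM. Macrophage and antigen-presentation genes held 0.118% ± 0.00716, with Cd74 at 498 ± 29.3 TPM and C1qc at 199 ± 8.17 TPM. Haemoglobin and other erythroid genes held 0.438% ± 0.0813, with Hba-a1 at 2131 ± 403 TPM. As a share of expected counts the erythroid list held 0.108%, below the endothelial list at 0.145%. Matrix genes held 0.0456% ± 0.00517, with Mgp at 276 ± 53.7 TPM. Smooth muscle genes held 0.0118% ± 0.00126 and Schwann and glial genes 0.00270% ± 0.000692. Of the 8 lymphocyte genes, only Cd79a reached 1 TPM in both libraries, and 6 of 10 cell cycle genes did so. No kidney gene reached 1 TPM in both, and only Aqp2 had enough counts to be tested. The proximal tubule gene Kap had 0 counts in each library, as did the pancreatic gene Cpa1. Cela1, an elastase gene of the pancreas list, was at 81.8 ± 0.134 TPM, whereas Cela2a and Cela3b were at 0.410 ± 0.240 and 0.245 ± 0.120 TPM.

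Transcript tables allowed the leading isoform of each gene of the steroidogenesis and chromaffin lists to be measured. Of 39 genes at 1 TPM or more in both libraries, 25 had more than 1 annotated transcript. In 21 of these 25 the same transcript led in both libraries, and in 11 it held over 90% of the gene's TPM in each. For Cyp21a1 it was a transcript with 10 exons, which held 95.5% ± 0.803 and for Cyp11a1 a transcript with 9 exons, at 92.9% ± 1.54. For Th it took 99.9% of the TPM. The leading share was lower for Scarb1 at 65.9% ± 0.590, for Por at 60.1% ± 0.0173 and for Soat1 at 39.7% ± 5.25. The leading transcript differed between the replicates for Stard4, Ddc, Scg2 and Slc6a2. Such shares rest on the authors' statistical split of reads between overlapping transcripts.

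The libraries were then compared with each other, gene by gene, to show where the replicates departed. Srd5a2, the steroid 5-alpha-reductase 2 gene (ENSMUSG00000038541.7, mm10 chromosome 17, 74016955 to 74047916), was 21.4-fold higher in replicate 1, at 1298 TPM in replicate 1 and 61.9 TPM in replicate 2. Its log2 ratio, replicate 1 over replicate 2, was 4.42 with an exact binomial 95% interval of 4.35 to 4.50. Susd3 stood at 143 and 4.86 TPM, the dopamine receptor gene Drd4 at 26.9 and 1.41 TPM, and the pancreatic colipase gene Clps at 53.4 and 1.63 TPM. Pgc (27.6 and 1.57 TPM), Tff1 (12.3 and 0.280 TPM) and Gkn1 (3.65 and 0.160 TPM), genes known from the stomach lining, were also higher in replicate 1, as were Psca (9.05 and 0.400 TPM) and Wfdc8 (1.81 and 0.0700 TPM). Tff1 had 121 counts against 3, a log2 ratio of 5.25 (3.90 to 7.78). The 10 lowest ratios held the plasma protein genes Ttr, Alb, Hpx and Apoa1 and the hepcidin gene Hamp2. Alb had 22 counts in replicate 1 and 441 in replicate 2, a log2 ratio of -4.15 (-4.87 to -3.56). Ttr had 0 counts in replicate 1 and 222 in replicate 2, at least 66.8-fold higher in replicate 2. Gm10925, Gm10698 and Gm10263 had fractional counts shared with other loci and are uncertain, as is 1 gene without a current name, while Gm13010 had 37 and 276 whole counts.

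**Figure D2:**
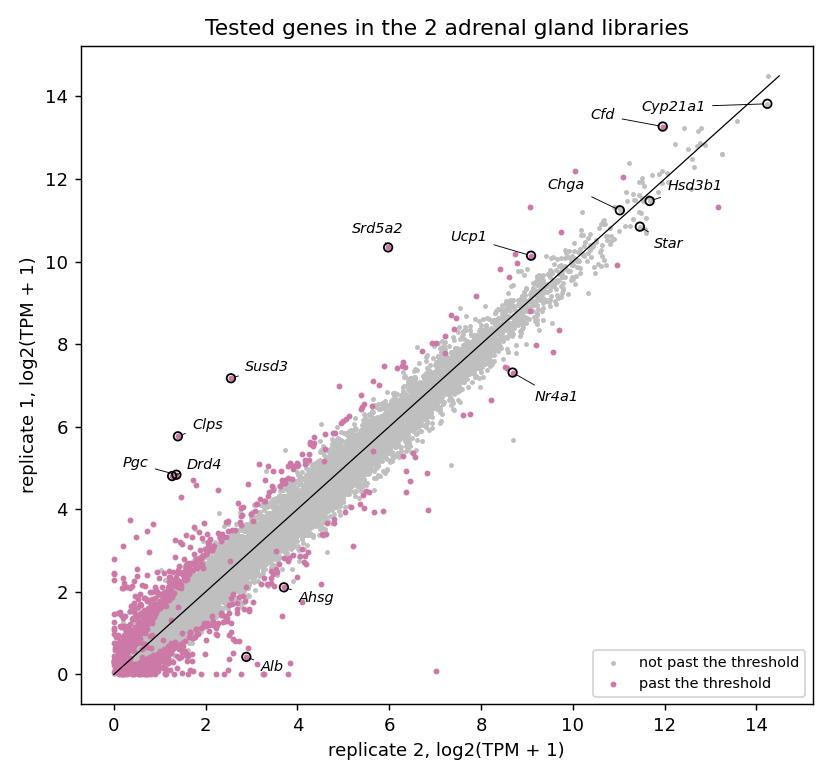
Each point is 1 of the 15814 tested genes, with log2(TPM + 1) of replicate 2 on the horizontal and of replicate 1 on the vertical axis, and the line marks equal values. Purple points passed the threshold of an adjusted p of 0.05 and 2-fold. Srd5a2, Susd3, Clps, Drd4 and Pgc lie above the line and Alb, Ahsg and Nr4a1 below it.

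Of the 15814 genes tested, 1092 (6.91%) differed at least 2-fold with a Benjamini-Hochberg adjusted p under 0.05 in the exact binomial test. Of these, 686 were higher in replicate 1 and 406 in replicate 2. Within 2-fold lay 92.4% of the tested genes. The test compares the reads of these 2 libraries and covers counting error only, so it does not replace replication. Y-linked genes and Xist also differed between the libraries, as given below. Differences of other genes and of lists therefore cannot be told apart from a possible difference in sex composition. Folds were called on scaled counts, so a pair of TPM values can give another fold. Without a minimum fold 9215 genes (58.3%) passed, and with an assumed biological coefficient of variation of 0.2 in edgeR's exact test 241 did. Counts of list members by adjusted p alone, given below, stand against that share of 58.3%. Scaled to spike-in counts, the median log2 ratio of all genes shifted by -0.43, and the split became 289 higher in replicate 1 and 1299 higher in replicate 2, so directions are relative to the other genes and a ratio between 0 and 0.43 changes sign under that scaling.

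Genes of cortical steroid and cholesterol metabolism were lower in replicate 1 as groups. In the cholesterol synthesis and uptake list the median log2 ratio was -0.65, below each of 10000 random lists matched on expression (percentile 0). Of its 20 tested members 2 passed the 2-fold threshold, over all genes and when adjusted over the list alone, among them Fdps (170 and 377 TPM). By adjusted p alone 17 were higher in replicate 2, Insig1 was higher in replicate 1 and 2 did not pass. The steroidogenesis list had a median of -0.29 (percentile 0.05). Of its 19 tested members 14 were higher in replicate 2 by adjusted p, 4 higher in replicate 1 (Fdx1, Fdxr, Lipe and Mrap) and 1 did not pass. Of these, Stard4 at 4.14 and 14.8 TPM was the 1 past 2-fold, also when adjusted over the list alone. The zona fasciculata list (median -0.49, percentile 0.5) and the X zone list (median -0.70, percentile 0.135) also lay below the random lists, with 0 members past 2-fold over all genes or adjusted over the list alone. The glomerulosa list (median -0.19, percentile 6.09) and the capsule list (median 0.03, percentile 60.65) did not. The fasciculata list shares Cyp11b1, Akr1b7 and Mc2r with the steroidogenesis list. In the same libraries the adipose list moved the other way.

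The adipose list and the chromaffin list were higher in replicate 1 as groups. The adipose list had a median log2 ratio of 0.84 (percentile 100), equal to 1.79-fold. Cfd (9884 and 3984 TPM) and Ucp1 (1129 and 544 TPM) passed 2-fold among 10 tested members, over all genes and adjusted over the list alone. By adjusted p 9 were higher in replicate 1, whereas the leptin gene Lep was lower (7.74 and 11.8 TPM). The chromaffin list had a median of 0.35 (percentile 99.99), which became -0.08 with spike-in scaling. Cartpt (9.07 and 2.27 TPM), Penk (15.5 and 6.08 TPM), Slc6a2 (4.99 and 2.53 TPM), Slc18a2 (8.33 and 4.02 TPM) and Chgb (290 and 147 TPM) passed 2-fold among its 20 tested members, 5 over all genes and 5 adjusted over the list alone. By adjusted p 13 were higher in replicate 1, 6 did not pass and Pnmt was higher in replicate 2 (381 and 593 TPM). The enzymes of catecholamine synthesis did not rise together, with log2 ratios of 0.19 for Th, 0.12 for Ddc, -0.0044 for Dbh and -0.60 for Pnmt. A list of sympathetic neuron genes, set up after its direction was seen, was also higher in replicate 1 (median 1.84). Which cells the rise of the chromaffin list came from was not tested. The endothelial list (median 0.26, percentile 98.4) and the Schwann and glial list (median 0.42, percentile 97.51) lay just above the random range, and both turned negative with spike-in scaling. The endothelial list was inside the range by its mean (0.19) and by log2(TPM + 1) (0.18), and the Schwann and glial list when random lists were also matched on length, so neither call is firm. Of the members of both lists 1 passed 2-fold, also adjusted over the list alone.

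The lists of heat shock and clock genes also lay outside the random range. The heat shock list had a median of -0.47 (percentile 0.01), with 7 of 8 members higher in replicate 2 by adjusted p and 0 past 2-fold, also adjusted over the list alone. Hspa8 was at 1811 and 2836 TPM, and Hspd1 was the exception. Hsph1 was at 6.75 and 23.9 TPM, although its scaled counts were 1.55-fold higher in replicate 2. The clock list had a median of -0.42 (percentile 0) and held opposite shifts. By adjusted p 11 members were higher in replicate 2, among them Per1 (41.5 and 75.5 TPM), Per3 (13.7 and 22.2 TPM) and Dbp (584 and 807 TPM). The other 4 were higher in replicate 1, among them Arntl (4.30 and 2.39 TPM) and Npas2 (12.2 and 7.16 TPM). Npas2 was the 1 member past 2-fold, at 2.03-fold by scaled counts, also adjusted over the list alone. Immediate early genes as a list stayed inside the random range (median 0.14, percentile 91.4), although Nr4a1 was higher in replicate 2 (158 and 412 TPM) and Atf3 in replicate 1 (2.78 and 1.12 TPM), also adjusted over the list alone.

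**Figure D3:**
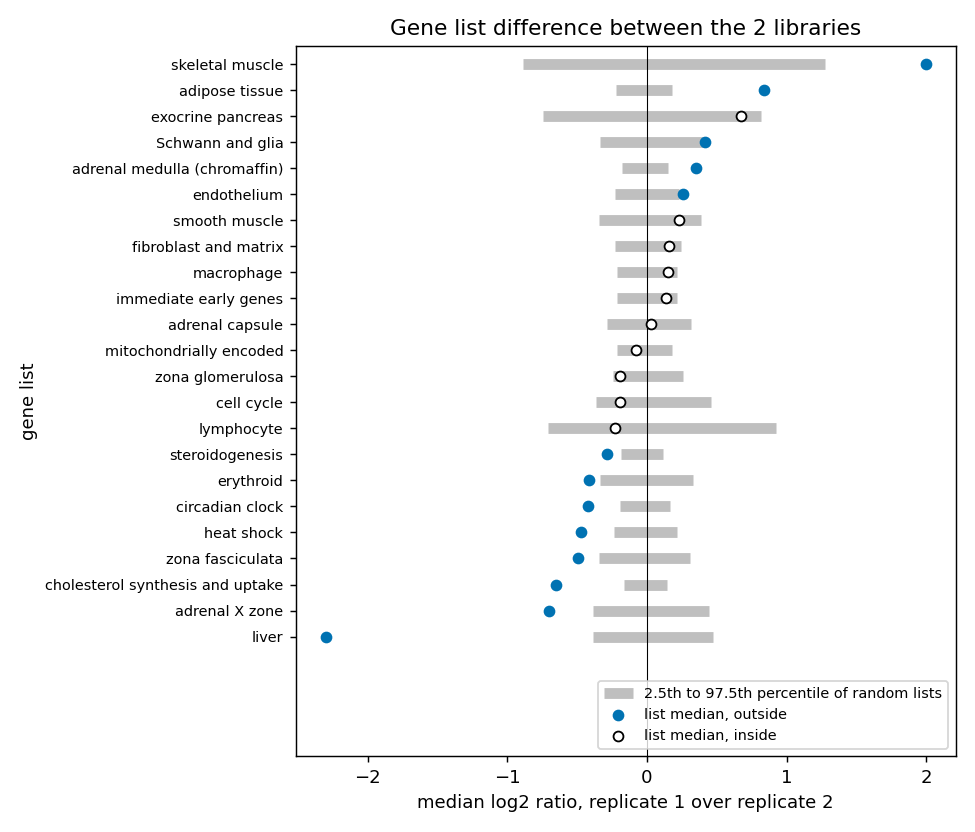
Each row is a gene list and the horizontal axis is its median log2 ratio, replicate 1 over replicate 2. Grey bars span the central 95% of 10000 matched random lists, filled points lie outside and open points inside. The sex chromosome and kidney lists are not drawn, and the liver list lies lowest at -2.30.

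Genes known from other organs and cell types also varied. The liver list had a median of -2.30 (percentile 0), or -2.24 with genes at 0 set to their bound of 3 counts. Alb, Apoa1, Ahsg, Cps1 and Serpina1a were higher in replicate 2 and Cyp2e1 in replicate 1 (39.2 and 16.2 TPM), all 6 past 2-fold over all genes and adjusted over the list alone. The erythroid list had a median of -0.41 (percentile 0.86), with 5 of 5 tested members higher in replicate 2 by adjusted p, 0 past 2-fold and 0 adjusted over the list alone. Its 4 globin genes share reads. Of 3 tested skeletal muscle genes, Acta1 (4.46 and 1.14 TPM) and Actn3 (0.460 and 0.150 TPM) were higher in replicate 1, also adjusted over the list alone, and the list's median was 1.99 (percentile 99.6). By the difference of log2(TPM + 1) it was 0.34 and inside the random range. The pancreas, smooth muscle, matrix, macrophage, lymphocyte, cell cycle and mitochondrially encoded lists lay inside the random range, with medians of 0.67, 0.23, 0.16, 0.15, -0.23, -0.19 and -0.08. Members of these past 2-fold were Clps, Cnn1, mt-Nd4l and mt-Co2, each also adjusted over its list alone, and the latter pair has fractional counts shared with other loci.

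Genes of the sex chromosomes differed sharply. Kdm5d (ENSMUSG00000056673.10, mm10 chromosome Y, 897788 to 956786) had 221 counts in replicate 1 and 0 in replicate 2, and was at least 81.6-fold higher in replicate 1. Eif2s3y, Ddx3y and Uty had 79, 32 and 26 counts in replicate 1 and 0 in replicate 2, at least 29.2-fold, 11.8-fold and 9.60-fold higher. These bounds set the 0 to 3 counts per library and cover counting error only. Xist, the RNA that coats the inactive X chromosome, was at 5.70 TPM in replicate 1 and 12.9 TPM in replicate 2, a log2 ratio of -1.15 (-1.21 to -1.10). All 5 passed 2-fold over all genes and adjusted over the list alone. The list's median was 6.10 (percentile 100), or 3.56 with the genes at 0 set to their bound. By the difference of log2(TPM + 1), which shrinks low genes, it was 0.30 and inside the random range. The 511 tested genes of the X chromosome had a median log2 ratio of -0.05 against -0.0035 for autosomal genes.

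Splicing and transcribed regions were listed in mm9 for the series as a whole, and these coordinates are separate from the mm10 gene positions above. The junction table held 378838 junctions with 35587975 reads. Of these, 107960 (28.5%) passed the authors' score at 0.1, with low values taken as more reproducible, and carried 98.4% of the reads, with a median of 46 reads each and a median span of 1142 bases. Reads in both of the name field's R1 and R2 values were present for 105192 (97.4%) of the passing junctions. Single reads accounted for 165208 of the listed junctions. The most used junction lay at mm9 chromosome 17, 34939182 to 34939249, with 334418 reads. The contig table held 404827 stretches of continuous coverage with a median length of 216 bases, covering 121.6 Mb in all. At a score of 0.1 or less, 220321 contigs (54.4%) remained, with a median length of 318 bases and 99.5% of the summed coverage. The contig with most coverage, at mm9 chromosome 17, 34931690 to 34941582 on the minus strand, held 1.56% of it and contains that junction. The contig next in rank, at mm9 chromosome 17, 39979921 to 39985775 on the plus strand, held 1.54%.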

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

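The tests in this part were chosen after the result was seen. Junction reads on chromosome Y, which none of the comparisons used, numbered 184 for R1 and 36 for R2. They were flagged because they exceed the 3 counts that a count of 0 allows, a low bar that tests no cause. The 8 of these junctions that passed the authors' score at 0.1 held 114 reads in R1 and 0 in R2. Which library R1 and R2 stand for is not stated, so these values are not set beside the gene tables by replicate.

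In the gene tables the 4 listed Y-linked genes had 358 counts in replicate 1 and 0 in replicate 2, and the limit of 3 counts in replicate 2 is 0.757% of the scaled level of replicate 1. The depth of replicate 2 was 1.11 times that of replicate 1, which argues against lower depth as the cause. A candidate explanation is a different sex composition of the 2 pools, although the labels describe mixed sex for both. The test of it on other protein-coding Y-linked genes was void, because these summed to 1 count over both libraries (Gm20826, 0 and 1). That test therefore cannot decide on the explanation. The listed genes themselves gave no Y-linked counts in replicate 2, within the limit of 3 counts. With 358 counts in replicate 1, they argue against an equal share of Y-linked RNA in both libraries. Xist in replicate 1 was at 45.0% of its scaled level in replicate 2. These values were known before the test.

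The sequence of the bacteriophage phiX174, listed as a row of the gene tables, took 0.271% of the expected counts in replicate 1 and 0.2735% in replicate 2. It was flagged by the same low bar.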

How the results depend on the processing

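Replicate numbers pair no groups here. No paired analysis was possible because there is only 1 group. Ratios between the libraries have no value without either library. Of the single-gene log2 ratios named for their size, all 120 recalculated values kept their direction and threshold under the scalings, posterior mean counts and assumed variation of 0.1 and 0.2, but not all kept their size. With posterior mean counts Gm10925 went from -10.5 to -1.05 and the gene without a current name from -9.27 to -3.46.

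The number of genes differing moved from 1092 to 462 with a summed count of at least 100 (327 higher in replicate 1, 135 in replicate 2). The 2549 genes with a summed count of 20 to 100, which this leaves out, had an SD of the log2 ratio of 1.32. Of them 28.8% lay 2-fold or more apart. The number of genes differing moved to 241 (133 and 108) with edgeR's exact test at a coefficient of variation of 0.2. With no minimum fold it moved to 9215 (4625 and 4590). Spike-in scaling gave 289 and 1299. Its cause was not tested.

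Of the list medians outside the random range, spike-in scaling reversed the chromaffin list to -0.078, the endothelial list to -0.17 and the Schwann and glial list to -0.014, as it shifts all genes by -0.43. The log2(TPM + 1) difference put the sex chromosome (0.30), skeletal muscle (0.34) and endothelial (0.18) lists inside the random range, and it shrinks low genes. The endothelial list was also inside by its mean (0.19), and the Schwann and glial list (0.42) when random lists were matched on length as well, an alternative added after seeing the data. The cause was not tested. The pancreas list left the range by its mean.

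As a share of expected counts 19 of 25 list shares moved, since counts weight long transcripts more. Steroidogenesis rose to 4.85% and cholesterol synthesis to 0.470%. The erythroid share fell to 0.108%, below the endothelial share of 0.145%, heat shock to 0.145% and the mitochondrially encoded genes to 1.15%. The correlation fell to 0.944 at a pseudocount of 0.01, a change called moved beyond 0.02. Without a score threshold 378838 junctions and 404827 contigs counted. Detected genes ranged from 12865 to 12881 in each library alone. FPKM moved 35 single-gene levels, being another unit, and left the ratios within the tissue at the reported values within their SD. Transcript counts in place of TPM moved 14 leading isoform shares. Posterior mean TPM moved 2 single-gene levels and 7 leading isoform shares.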

Other observations

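In this part, the tests of the lower cortical share and of gene length were chosen after the result was seen, as was the sympathetic neuron list. Neuronal genes that the report does not cover differed together. After Tubb3, Prph, Nefl and Ecel1 were seen among the large ratios, a list of 10 sympathetic neuron genes was set up around them, so its direction is not independent evidence. All 10 were higher in replicate 1 by adjusted p in the exact binomial test, 8 of them at least 2-fold over all genes and 8 adjusted over the list alone. The median log2 ratio was 1.84 (percentile 100). Tubb3, a neuronal tubulin, was at 21.2 and 3.79 TPM, the intermediate filament gene Prph at 8.30 and 1.70 TPM and Nefl at 4.60 and 0.910 TPM. Uchl1, known from neurons and neuroendocrine cells, was at 130 and 84.5 TPM and the nicotinic receptor gene Chrna3 at 15.9 and 8.53 TPM.

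Adipose markers were higher in replicate 1. A lower share of cortical RNA would raise markers of cells outside the cortex. The adipose median exceeded that of 24 endothelial, macrophage and erythroid genes by 0.79 (bootstrap standard error 0.13). This error rests on 10 and 24 genes in these libraries and does not measure spread between replicates. Cells with these 24 markers may lie within the cortex, and the erythroid list itself was lower in replicate 1 (median -0.41). The gap therefore shows a larger rise of the adipose list than of these genes, and cannot decide on the cortical share. A candidate explanation is more adipose tissue RNA in replicate 1. A second list of 12 adipose genes, fixed before its values were seen, had a median of 0.83 at percentile 100, with Adrb3 at 1004 and 439 TPM and Cox8b at 874 and 449 TPM. All 12 had a positive ratio, 11 passed by adjusted p, 1 at 2-fold (also adjusted over the list alone), and all 12 reached 1 TPM in both libraries. Adrenal cells may express some of them, and Lep went the other way, so the source stays a hypothesis.

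Members of the clock list passed by adjusted p in opposite directions, 4 higher in replicate 1 and 11 lower. These arms were split by the sign of the ratio, so a gap between their medians is positive by construction and shows nothing by itself. The medians of 10 groups of genes of like length ran from -0.094 to 0.049. After these were subtracted the gap went from 1.25 to 1.29, and the 95% intervals of the same 4 genes lay above 0 and those of the 11 below, which argues against a length trend as the whole cause. The collection times of the pools may have differed. Of 4 further clock-linked genes with a direction set before their values were seen, Usp2, Wee1 and Bhlhe40 had log2 ratios of -0.32, -0.44 and -0.87 and Nfil3 0.06, which did not pass by itself. Their median in the expected direction lay at percentile 98.25 of random lists. No times of collection are given in the labels used here, and no other biological explanation was tested, as the design has 1 group.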
